A study of Mus musculus with 6 samples.

How the data were processed

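The series measured messenger RNA by sequencing (mRNA-seq) in mouse bone marrow-derived dendritic cells, which are immune cells grown from bone marrow progenitors in the cytokine GM-CSF. Per the labels' protocols, marrow came from female C57BL/6 mice aged 6 to 8 weeks and was grown in medium with dialyzed serum and GM-CSF at 15 ng/mL. Fresh medium was given on days 2 and 4 and RNA was taken with TRIzol on day 5. The 2 groups were medium without queuine (0Q) and medium with queuine at 100 nM (100Q), with 3 libraries in each. Queuine is the base from which cells make queuosine, a modified nucleoside at the wobble position of the tRNAs for Asn, Asp, His and Tyr. The labels say that cells were plated in triplicate and do not say whether the wells came from separate animals, so p-values measure only the spread between these cultures, which may be partly technical.

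The authors deposited 1 table of expected counts per gene, as RSEM estimates them per the submitters' processing notes, with a column for each of the 6 libraries and no pooling or normalization. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR and quantified with RSEM on mm39 (GRCm39), and the series' design text names the NextSeq 550 sequencer. Tool versions, the annotation release and the strandedness of the libraries are not given in the sources used here. Because RSEM divides ambiguous reads between genes, 5.51% to 10.5% of the values in a library were not whole. That share is over all 57132 genes, and only 13752 to 18284 of them were detected in a library. Among genes with counts the share was therefore higher. The division of reads can shift values between near-identical genes such as Hba-a1 and Hba-a2, and values of such genes are uncertain. Genes that overlap or lie antisense to each other may also share reads.

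The table listed 57132 Ensembl gene identifiers. Symbols, positions and gene types were taken from GENCODE mouse release 39 on the same build, and 502 identifiers had no match there and kept their identifier as name. No entry lacked a gene, and 0 columns were left unused. Expected counts were rounded to whole numbers before testing. Total counts were 5720248, 6755367 and 3675918 in 0Q replicates 1, 2 and 3 and 5296149, 4484785 and 19386533 in 100Q replicates 1, 2 and 3. A floor of 3 counts corresponded to 0.155 CPM in the deepest library and 0.816 CPM in the shallowest, taken on these full totals without scaling. Without molecular identifiers reads are not independent molecules, so such floors cover counting error only. No pair of libraries agreed within sampling noise, with a chi-square per gene between 8.61 and 19.1, so none was a copy of another. Noise between preparations was not modelled, and the 6 were taken as separate samples from their labels.

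Genes were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr with default settings, TMM factors, robust quasi-likelihood fits (glmQLFit) and glmQLFTest for 100Q relative to 0Q, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the absolute log2 fold change divided by the root of the F statistic, and 95% confidence intervals used the total degrees of freedom of the fit. CPM values used each library's total over the tested genes, scaled by the TMM factors. Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 31 of 32 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. The codon measure used 1 longest coding sequence per gene from the same annotation, 21493 in all. For each library it gave the share of codons ending in U among the Asn, Asp, His and Tyr codons (NAU among NAU plus NAC), weighted by counts per kilobase, and groups were compared with an exact two-sided permutation test. Across genes, fold change was correlated with the NAU share of genes with at least 20 such codons.

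The comparison, the tests, the lists with their members, the rule for named genes and all alternatives except those stated otherwise in the closing section were chosen before the data were examined. The rule named the genes with the largest changes among those past the threshold, or, with fewer than 5 in a direction, the 5 with the smallest p. Predicted genes and pseudogenes were passed over, 1 among the higher and 3 among the lower genes. It also named the 2 members with the smallest p and the most abundant member of each list, and a fixed set for MHC class II, proliferation and queuosine handling. Some genes that the rule names are not reported here. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters, the replicate number as a block and each library left out.

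The edgeR and camera steps were tested on simulated data with the real means, library sizes and 10554 genes, in 5 draws with 200 changed genes each. For 100Q against 0Q, genes at 100 CPM or more were recovered in 40.5% of cases at 1.5-fold, 92.2% at 2-fold and 97.9% at 4-fold. Over all genes the shares were 8.36%, 33.1% and 62.4%, with 4 false calls per draw on average. A shift of 0.4 (log2) in the MHC class II, mitosis or DNA replication list was called in 5 of 5 draws, and a shift of 0.2 in 2 or 3 of 5. Genes were drawn independently of each other, whereas the estimated correlations within these lists in the data were 0.150, 0.072 and 0.045. The list recovery therefore holds for uncorrelated members only. Figures were drawn with matplotlib 3.10.9.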

Results

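To ask how queuine supply affects the transcriptome of dendritic cells, mRNA-seq was performed on mouse bone marrow cultures grown for 5 days without queuine (0Q) or with 100 nM queuine (100Q), 3 libraries per group. The series title names codon usage, cell proliferation and MHC class II expression as the subjects of the study. The libraries used here measured mRNA levels only. Translation of codons, MHC class II protein and cell growth were not measured by them, so the values below do not bear on those. Libraries held 3675918 to 6755367 counts in 0Q and 4484785 to 19386533 in 100Q, and 13752 to 15419 and 14641 to 18284 genes were detected. The most abundant transcripts were those of Ccl6, a chemokine, Ftl1, a ferritin light chain, and Prdx1, a peroxiredoxin, at mean values of 36754, 34489 and 22383 CPM over the 6 libraries. Lyz2, the lysozyme of myeloid cells, had 17825 ± 906 CPM in 0Q and 18473 ± 1837 CPM in 100Q (SD, n = 3 each). The 20 most abundant genes took 25.3% to 27.4% of each library.

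No single gene passed the test between cultures with and without queuine. The MHC class II list also holds regulators and antigen presentation genes such as the protease Ctss. Of its 17 tested genes, 14 had estimates above 0 in 100Q, with a median log2 fold change of 0.15, and the list did not pass its test. The 6 members at 100 CPM or more had a median of 0.03 and the 11 others 0.28. H2-Aa had 577 ± 91.9 CPM in 0Q and 580.3 ± 76.5 CPM in 100Q, and the proliferation marker Mki67 had 102 ± 8.16 and 104 ± 17.3 CPM (SD, n = 3 each). By camera with a preset correlation, granulocyte lineage markers were lower in 100Q, with a median log2 fold change of -0.20 over 18 members, and cytosolic ribosomal proteins were lower by a smaller amount, with a median of -0.12 over 28 members. Neither list passed by camera with an estimated correlation (adjusted p = 0.700 for both, unadjusted p = 0.0430 and 0.343). Adjustment gave many of the 31 lists this same value of 0.700.

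Of 10554 genes tested with edgeR's quasi-likelihood test, 0 reached an adjusted p under 0.05, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 309 genes, 187 higher and 122 lower in 100Q, which is 2.93% of the tested genes where 5% would arise by chance. DESeq2 called 0 genes, with 356 at an unadjusted p under 0.05, and limma-voom called 0, with 310. Their smallest adjusted p was 0.135 and 0.999. Without a filter on low counts edgeR's smallest adjusted p was 0.0716. The 3 libraries of one group lay wholly above those of the other for 870 genes, or 8.24%, against 10% by chance. Precision depended on abundance. The median half-width of the 95% interval of a log2 fold change was 0.23 for the 153 genes at 1000 CPM or more, 0.31 for the 1175 genes from 100 to 1000 CPM, 0.65 for the 4928 genes from 10 to 100 CPM and 1.36 for the 4298 genes below 10 CPM. The interval lay within 1.5-fold in either direction for 88.3% of the genes from 100 to 1000 CPM and for 98.7% of those above. In both of these abundance classes 0 genes had an estimated change over 2-fold, whereas below 10 CPM 531 did.

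**Figure D1:**
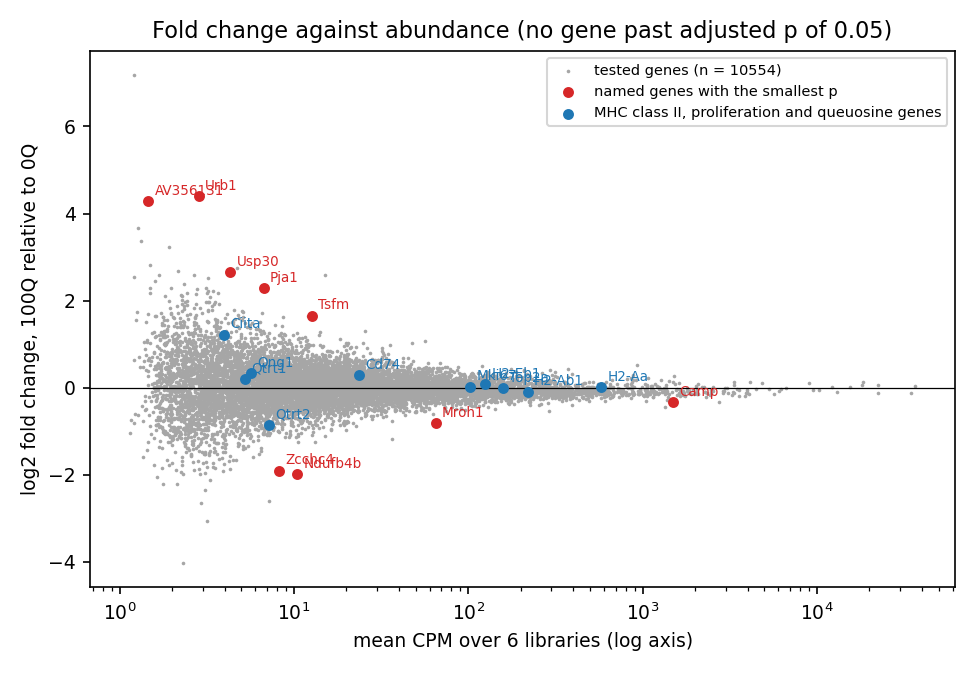
Log2 fold change of 100Q relative to 0Q (vertical axis) against mean CPM over the 6 libraries (horizontal axis, logarithmic) for the 10554 tested genes, each point a gene. Red points are the genes named in the text among those with the smallest p in each direction and blue points the MHC class II, proliferation and queuosine genes; the scatter narrows with abundance, and 0 genes passed an adjusted p of 0.05.

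MHC class II molecules present peptides to CD4 T cells. H2-Aa (ENSMUSG00000036594, chromosome 17, 34493404 to 34506798, GRCm39), which encodes the alpha chain of I-A, had a log2 fold change of 0.01 (SE 0.14, 95% interval -0.28 to 0.30, edgeR adjusted p = 0.999). For its partner H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34476663 to 34488393) the value was -0.09 (SE 0.13), with 226 ± 10.9 CPM in 0Q and 213 ± 11.9 CPM in 100Q. H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34504236 to 34535648) had 122 ± 3.89 and 129 ± 15.5 CPM and a log2 fold change of 0.08 (SE 0.15). Cd74 (ENSMUSG00000024610, chromosome 18, 60936899 to 60945731), the invariant chain that guides class II molecules to the endosome, had 21.3 ± 1.43 and 26.2 ± 1.74 CPM, a log2 fold change of 0.30 (SE 0.28). Its level was far below that of H2-Aa in all 6 libraries, and it is not known whether its reads were lost in quantification, so the level and the fold change are uncertain. Ciita (ENSMUSG00000022504, chromosome 16, 10297923 to 10347694), the master regulator of class II transcription, had 2.30 ± 2.54 and 5.62 ± 0.21 CPM, a log2 fold change of 1.22 (SE 0.73, 95% interval -0.32 to 2.75, edgeR adjusted p = 0.999). The 3 libraries of 100Q lay above those of 0Q for Ciita and Cd74, and by chance 10% of genes show no overlap in one direction or the other. For Ciita the nearest libraries had 5.22 CPM (0Q replicate 2) and 5.48 CPM (100Q replicate 2). A floor of 3 counts corresponded to 0.444 and 0.669 CPM in these libraries, so the separation lay within counting error. For Cd74 the nearest had 22.9 CPM (0Q replicate 1) and 24.9 CPM (100Q replicate 1). Ctss, the protease that trims the invariant chain, was the most abundant member at 6646 ± 679 and 6597 ± 569 CPM. Of the 17 tested members of the list, 14 had estimates above 0 and 3 below, with a median of 0.15. Over the list, 0 members passed when adjusted over the list alone and 0 over all genes, and camera gave an adjusted p of 0.116 (adjusted p = 0.700 with an estimated correlation). Leaving out 0Q replicate 1 made this list pass camera's threshold, with a median of 0.28 and an adjusted p of 0.00322, as did 3 other settings given in the closing section. Its adjusted p over the other 5 omissions lay between 0.0784 and 0.751, and without 0Q replicate 3 its median was 0.06.

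**Figure D2:**
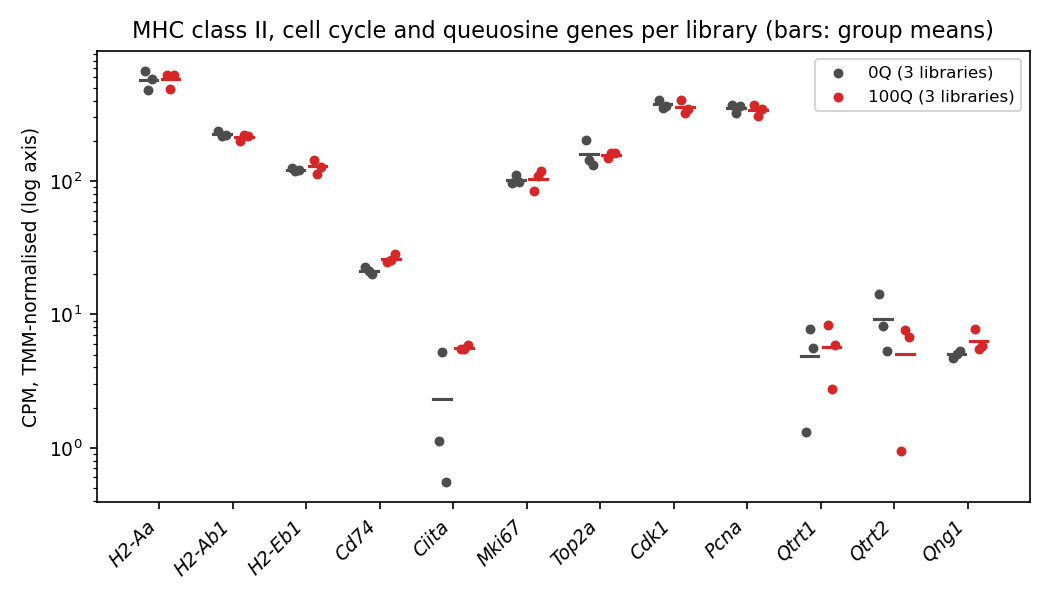
TMM-normalised CPM (vertical axis, logarithmic) of MHC class II, cell cycle and queuosine genes in each of the 3 libraries of 0Q (grey) and 100Q (red), with bars at group means. The groups do not overlap for Cd74, Ciita and Qng1 and overlap for the other genes shown, and Qtrt1, Qtrt2 and Qng1 lie mostly below 10 CPM. The nearest libraries of 0Q and 100Q are at 5.22 and 5.48 CPM for Ciita and at 5.28 and 5.48 CPM for Qng1.

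Proliferation was read from 2 lists. Mki67, a marker of cycling cells, had a log2 fold change of 0.03 (SE 0.17), and Top2a, the topoisomerase of dividing cells, -0.01 (SE 0.16) at 159 ± 37.8 and 158 ± 7.82 CPM. Of 27 mitosis and G2/M genes, 12 had estimates above 0 and 15 below, with a median of -0.01 and a camera adjusted p of 0.990. With 1 library left out that median ranged from -0.09 (without 100Q replicate 3) to 0.04 (without 0Q replicate 1). Cdk1, the mitotic kinase, had 375 ± 30.1 and 359 ± 41.0 CPM. Of 30 DNA replication and G1/S genes, 22 had estimates below 0, with a median of -0.07 and a camera adjusted p of 0.234 (adjusted p = 0.700 with an estimated correlation). With 1 library left out this median ranged from -0.14 (without 0Q replicate 2) to -0.02 (without 0Q replicate 1), and it was -0.12 without 100Q replicate 3 (adjusted p = 0.0578). Pcna, the replication clamp, had 355 ± 26.6 and 343 ± 32.1 CPM, and Rrm2, a subunit of ribonucleotide reductase, had a log2 fold change of -0.24 (SE 0.14). In both lists 0 members passed when adjusted over the list alone, and 0 over all genes.

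The granulocyte list holds genes of neutrophils and their precursors, and 15 of its 18 members had estimates below 0. Its camera adjusted p was 3.15e-06 with the preset correlation and 0.700 with the estimated correlation of 0.170. The members' mean log2 of CPM plus 1 was 7.71 ± 0.13 in 0Q and 7.55 ± 0.04 in 100Q (exact two-sided permutation p = 0.2). The groups overlapped, with 0Q replicate 3 at 7.57 and 100Q from 7.51 to 7.59. Camp, the cathelicidin of secondary granules (ENSMUSG00000038357, chromosome 9, 109676442 to 109678685), had 1651 ± 124 CPM in 0Q and 1320.4 ± 75.8 CPM in 100Q, a log2 fold change of -0.32 (SE 0.10, unadjusted p = 0.00620 by edgeR). Ly6g, a neutrophil surface antigen, had 106 ± 20.8 and 77.0 ± 7.36 CPM, and S100a9, a calcium-binding protein of neutrophils and monocytes, had 5933 ± 254 and 5385 ± 603 CPM. Adjusted over the list alone, 0 members passed, and the smallest such p was 0.112. Without 0Q replicate 1 the list's camera adjusted p was 0.0617, with a median of -0.15. Of the 28 ribosomal protein genes, 25 had estimates below 0. The camera adjusted p was 0.00161 with the preset correlation and 0.700 with an estimated correlation. By the exact permutation test on the members' mean log2 of CPM plus 1, p was 0.5. Rps9 had a log2 fold change of -0.17 (SE 0.11), and 0 members passed when adjusted over the list alone or over all genes. The ribosomal list's median was -0.04 without 0Q replicate 1 (adjusted p = 0.957), -0.10 without 100Q replicate 2 (adjusted p = 0.0784) and -0.19 without 0Q replicate 2. By camera that list also did not pass without a filter on low counts (adjusted p = 0.487). With each library's transcript length trend removed its median was -0.05 (camera adjusted p = 0.247). In 0Q replicate 1 nuclear rRNA took 0.244% of counts, against 0.120% to 0.141% in the other 5 libraries, and log2 deviations correlated with transcript length at a rho of -0.27 across genes.

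**Figure D3:**
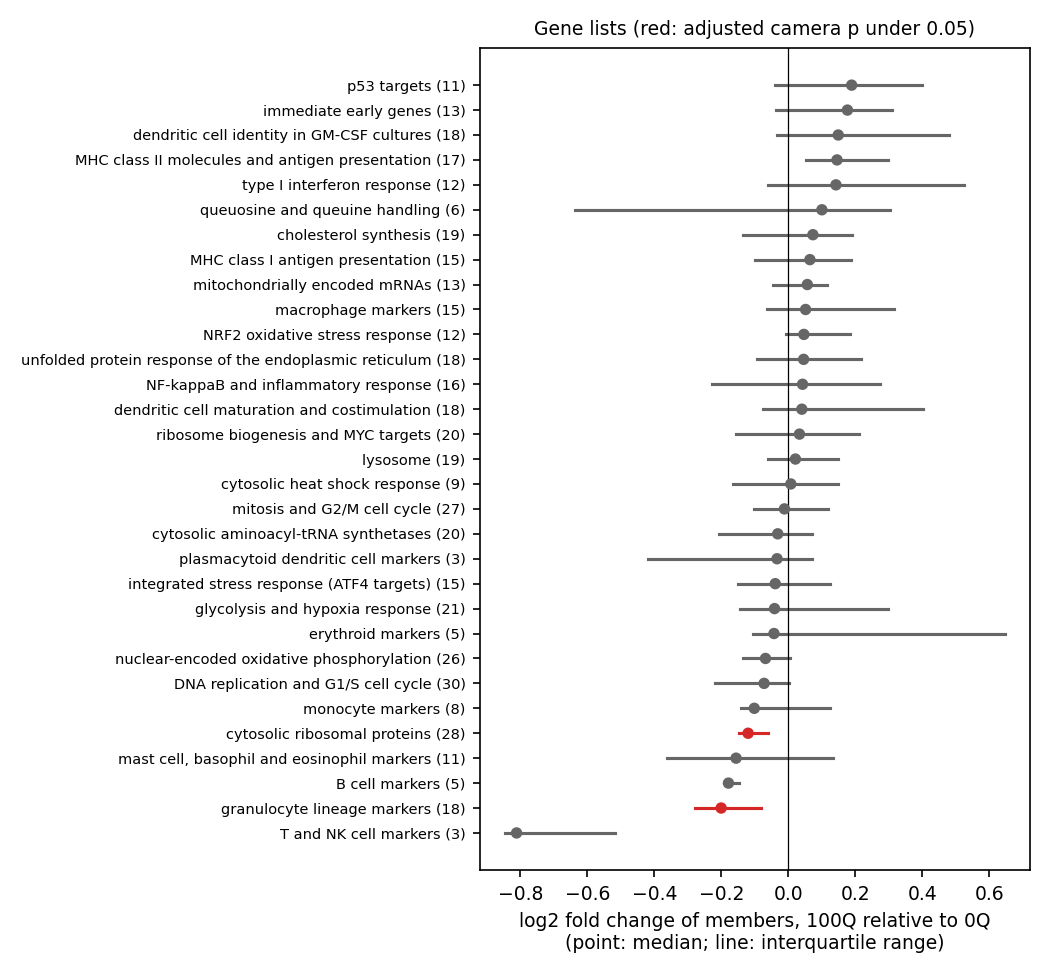
Median (point) and interquartile range (line) of the members' log2 fold change, 100Q relative to 0Q (horizontal axis), for the 31 tested gene lists, with tested members in brackets. The granulocyte and ribosomal protein lists (red) passed camera's adjusted p of 0.05 with the preset correlation, at medians of -0.20 and -0.12, and 0 lists passed with an estimated correlation.

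Enzymes that insert or salvage queuine were expressed at low levels. Qtrt1 and Qtrt2, the subunits of the enzyme that exchanges guanine for queuine in tRNA, had 4.88 ± 3.27 and 9.21 ± 4.53 CPM in 0Q and 5.66 ± 2.82 and 5.08 ± 3.60 CPM in 100Q. Qng1, an enzyme of queuine salvage, had 5.03 ± 0.28 and 6.34 ± 1.26 CPM. Slc35f2, a queuine transporter, had 0 counts in all 6 libraries, which allows up to 0.155 CPM in the deepest library. The 6 tested members of the queuosine list split 3 above and 3 below 0, and below 10 CPM simulated 2-fold changes were recovered in 0.735% of cases, so most changes of that size would have been missed in these libraries. For cytosolic aminoacyl-tRNA synthetases the median was -0.03 over 20 members, from -0.09 (without 0Q replicate 1) to 0.01 (without 100Q replicate 3) with 1 library left out, with Farsb at 177 ± 22.6 and 151 ± 20.2 CPM.

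The use of queuosine codons in the transcriptome was close in both groups, and the test found no difference that this design could resolve. Codons ending in U made up 45.5% ± 0.126 of the NAU plus NAC codons in 0Q and 45.5% ± 0.0504 in 100Q (SD, n = 3 each), a difference of 0.0644 percentage points (exact two-sided permutation p = 0.5, where 0.1 is the smallest p that 3 against 3 libraries allow). This difference was smaller than the SD of the 0Q libraries and larger than that of the 100Q libraries. It was 0.0693 points with raw counts as weights and -0.00595 points without the 20 most abundant genes, each at an exact p of 0.9. Across 8755 genes, which are not independent replicates, the log2 fold change had a Spearman rho of -0.04 with the NAU share of the gene, and of -0.01 given the GC content at the wobble positions of its other codons.

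The genes with the smallest p were mostly of low abundance, and each had an adjusted p of 0.999 by edgeR. On the higher side, Tsfm, a mitochondrial translation elongation factor (chromosome 10, 126847441 to 126866717), had 6.03 ± 1.13 CPM in 0Q and 19.2 ± 6.47 CPM in 100Q. Usp30, a mitochondrial deubiquitinase (chromosome 5, 114203522 to 114262781), had 1.11 ± 0.66 and 7.53 ± 4.66 CPM, and Pja1, a ubiquitin ligase (chromosome X, 98509340 to 98514879), 2.20 ± 1.78 and 11.2 ± 7.19 CPM. Urb1, a ribosome biogenesis factor (chromosome 16, 90548415 to 90607301), had 0.22 ± 0.20 and 5.45 ± 2.98 CPM, and the long noncoding RNA AV356131 (chromosome 7, 116042340 to 116097743) had 0.13 ± 0.22 and 2.80 ± 0.95 CPM, values that rest on 4 and 2 counts over the 0Q libraries. On the lower side, Mroh1 (chromosome 15, 76264450 to 76337258) had 82.9 ± 11.03 and 47.0 ± 4.53 CPM, a log2 fold change of -0.81 (SE 0.19). Zcchc4, a methyltransferase of 28S rRNA (chromosome 5, 52932751 to 52982012), had 12.95 ± 6.82 and 3.48 ± 1.88 CPM. Ndufb4b (chromosome 19, 25010486 to 25010967), annotated as a noncoding gene, had 16.7 ± 7.43 and 4.09 ± 1.23 CPM, and its value is uncertain because reads could be divided between it and its relative Ndufb4.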

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

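Thinning of 100Q replicate 3 to the depth of the others and removal of each library's transcript length trend were chosen after the data were seen, and all other settings here were planned. The count of genes past the threshold was 0 in every setting except without 0Q replicate 1 (2, Gvin2 and Gm46542) and without 0Q replicate 2 (1, Gm2446), so it ranged from 0 to 2 over omitted libraries. These 3 genes are named after their values were seen. The count of lists was 2, ranged from 1 to 4 over omitted libraries, and was 0 by camera with an estimated correlation and 0 by fry. The MHC class II median of 0.15 was 0.18 with library totals alone (adjusted p 0.0393), 0.24 without a filter on low counts (adjusted p 0.00194) and 0.17 with the length trend removed (adjusted p 0.0145), and ranged from 0.057 to 0.28 over omitted libraries. The cause was not tested. The ribosomal list no longer passed without a filter (-0.11, adjusted p 0.487). Mitochondrially encoded mRNAs passed without a filter (0.07), with the length trend removed (0.13) and without 100Q replicate 1 (0.10), and nuclear oxidative phosphorylation genes without 0Q replicate 2 (-0.11) and without 100Q replicate 1 (-0.08), all with the preset correlation; as reported, both had an adjusted p = 0.700 with an estimated correlation. List medians changed sign in 34 of 186 cases with a library left out in 1 of 31 with the replicate number as a block and in 15 of 279 in the other settings. Over 917 values of named genes in those settings 17 changed sign, over 102 with the block 1 did, and over 611 with a library left out 40 did, with 0 called. The mitosis and DNA replication lists did not pass in any setting, and their medians ranged over omitted libraries from -0.09 to 0.04 and from -0.14 to -0.02. The exact codon test cannot go under 0.1, so its calls show nothing. The difference in NAU share of 0.0644 points was -0.00595 without the 20 most abundant genes and ranged from 0.00430 (without 0Q replicate 1) to 0.130 (without 0Q replicate 3), and the rho with NAU share ranged from -0.08 to -0.01 over omitted libraries. With the replicate number as a block, 0 genes and 2 lists passed, and it changed no call. Libraries with the same number had deviations correlated at 0.03, 0.08 and -0.01, and those with different numbers at -0.10 to 0.09. These values cannot tell whether the numbers pair the samples. Below 10 CPM the simulated 2-fold changes were recovered in 0.735% of cases. The variance of genes at 10 to 20 counts was 6.52 (0Q) and 4.53 (100Q) times the counting variance, and other depths were not simulated. For this measure 100Q was thinned to its shallowest library and 0Q was only rescaled, so the values of the groups are not directly comparable.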

Other observations

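The tests of chance and of the transcript length trend were chosen after the results were seen, while the lists and their camera tests were planned.

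Dendritic cell identity genes had a median log2 fold change of 0.15 over 18 members (camera adjusted p = 0.261), which ranged from 0.06 (without 100Q replicate 3) to 0.27 (without 100Q replicate 2) with 1 library left out. Itgax, which encodes CD11c, had 98.6 ± 26.8 CPM in 0Q and 140.2 ± 14.7 CPM in 100Q, and Kmo 12.9 ± 3.50 and 6.21 ± 0.98 CPM. In the maturation list the median was 0.04 over 18 members, from -0.05 (without 0Q replicate 2) to 0.20 (without 0Q replicate 1) with 1 library left out, with Ccl17, a chemokine for T cells, at 255 ± 25.4 and 335 ± 65.4 CPM and the costimulatory molecule Cd86 at 18.3 ± 6.03 and 9.51 ± 2.00 CPM. Macrophage markers had a median of 0.05 over 15 members (adjusted p = 0.234), ranging from 0.01 (without 100Q replicate 1) to 0.17 (without 0Q replicate 1) with 1 library left out, with Arg1 at 1.11 ± 0.84 and 5.19 ± 2.10 CPM. Medians were -0.10 for monocyte markers and -0.16 for mast cell, basophil and eosinophil markers, whose Mcpt8 had 139 ± 25.2 and 111 ± 7.42 CPM. With 1 library left out these medians ranged from -0.18 (without 100Q replicate 3) to -0.02 (without 100Q replicate 1) and from -0.25 (without 100Q replicate 3) to -0.07 (without 100Q replicate 2). They were -0.18 for B cell, -0.81 for T and NK cell, -0.04 for erythroid (where camera's direction and the mean of 0.24 were upward) and -0.03 for plasmacytoid dendritic cell markers, from 5, 3, 5 and 3 tested members. With 1 library left out the T and NK cell median ranged from -1.26 (without 100Q replicate 2) to -0.19 (without 0Q replicate 2) and the B cell median from -0.29 (without 0Q replicate 3) to -0.03 (without 0Q replicate 1). The plasmacytoid median ranged from -0.42 (without 100Q replicate 2) to 0.26 (without 100Q replicate 1) and the erythroid median from -0.15 (without 100Q replicate 1) to 0.09 (without 100Q replicate 2). Of the stromal markers 1, Pecam1, was tested, at 19.1 ± 6.97 and 13.3 ± 3.29 CPM. In each of these lists 0 members passed when adjusted over the list alone, and 0 over all genes.

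Stress and metabolic lists did not pass either. Medians were 0.19 for p53 targets, 0.18 for immediate early genes, 0.14 for the type I interferon response, 0.04 for the inflammatory response, 0.05 for the unfolded protein response, 0.01 for the heat shock response, 0.05 for the NRF2 response and -0.04 for ATF4 targets. With 1 library left out (named in brackets), the p53 median ranged from -0.07 (100Q replicate 2) to 0.45 (100Q replicate 3), the immediate early median from -0.04 (100Q replicate 2) to 0.25 (100Q replicate 3) and the interferon median from 0.02 (100Q replicate 3) to 0.37 (0Q replicate 1). The inflammatory median ranged from -0.02 (100Q replicate 3) to 0.08 (100Q replicate 1), the unfolded protein median from 0.02 (0Q replicate 1) to 0.12 (0Q replicate 2) and the heat shock median from -0.08 (100Q replicate 3) to 0.05 (100Q replicate 2). The NRF2 median ranged from 0.00 (100Q replicate 1) to 0.11 (100Q replicate 2) and the ATF4 median from -0.05 (100Q replicate 2) to 0.04 (100Q replicate 1). The medians for cholesterol synthesis, MHC class I presentation, mitochondrially encoded mRNAs, ribosome biogenesis and lysosome were 0.07, 0.06, 0.06, 0.03 and 0.02, and those for glycolysis and nuclear oxidative phosphorylation were -0.04 and -0.07. With 1 library left out, cholesterol ranged from -0.03 (0Q replicate 1) to 0.20 (0Q replicate 3), MHC class I from -0.01 (0Q replicate 1) to 0.14 (0Q replicate 2) and mitochondrially encoded mRNAs from 0.01 (100Q replicate 2) to 0.10 (100Q replicate 1, where that list passed with the preset correlation). Ribosome biogenesis ranged from -0.02 (100Q replicate 2) to 0.09 (0Q replicate 2), lysosome from -0.08 (0Q replicate 2) to 0.10 (0Q replicate 1), glycolysis from -0.04 (100Q replicate 3) to 0.02 (0Q replicate 2) and nuclear oxidative phosphorylation from -0.12 (100Q replicate 3) to -0.03 (100Q replicate 2), and that list passed without 0Q replicate 2 (-0.11) and without 100Q replicate 1 (-0.08), with the preset correlation. As reported, the lists of mitochondrially encoded mRNAs and nuclear oxidative phosphorylation both had an adjusted p of 0.700 by camera with an estimated correlation. For the heat shock and cholesterol lists camera's direction was downward, and for glycolysis upward, against the sign of the median. Fos had 2.96 ± 0.46 and 7.74 ± 1.79 CPM, and Ndufs1, a complex I subunit, 99.2 ± 12.2 and 70.5 ± 11.95 CPM. In each of these lists 0 members passed when adjusted over the list alone, and 0 over all genes.

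The first pattern is the lower granulocyte list, which did not pass with an estimated correlation (adjusted p = 0.700) or without 0Q replicate 1 (adjusted p = 0.0617). With each library's transcript length trend removed, the median went from -0.20 (interquartile range -0.28 to -0.08) to -0.14 (-0.22 to -0.06). It moved toward 0, and 15 of 18 members were then below 0. The list still passed camera (adjusted p = 0.000264, preset correlation). The removal was run with the preset correlation only, so that pass cannot decide on a length trend between libraries as the whole cause. The 9 members at 100 CPM or more had a median of -0.22, all below 0, and the 9 others -0.06, with 3 above 0, and that difference was not tested. A lower share of granulocyte-lineage cells and a change of expression within them both stay open as untested, since a test of a common change among members (chi-square per degree of freedom 0.653), chosen after the results were seen, was dropped because 29 of the 30 other lists also met its limit of 2. The splits of 6 libraries, 10 in all, are too few for a share under 0.05; the real absolute median of 0.20 was the highest, in 1 split, the highest other was 0.15, and the list was called in 3 of them.

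The second pattern is the lower ribosomal protein list, which did not pass with an estimated correlation (adjusted p = 0.700), without 0Q replicate 1 (adjusted p = 0.957) or without 100Q replicate 2 (adjusted p = 0.0784). Its members have short transcripts, with a median of 1340 nt against 2820 nt for all genes at 20 CPM or more. The granulocyte and MHC class II lists also have short transcripts, with medians of 1097.5 and 1462 nt. The deviation of a library correlated with transcript length at a Spearman rho of -0.27 (0Q replicate 1) to 0.22 (0Q replicate 2) across genes. On the second principal component 0Q replicate 1 lay at 67.1 and the other libraries between -34.8 and 0.46, and on the first 0Q replicate 3 lay apart at -73.1. With each library's length trend removed, the median went from -0.12 (interquartile range -0.15 to -0.06) to -0.05 (-0.09 to 0.00) and the list no longer passed because its members moved toward 0 (adjusted p = 0.247), so a length trend could account for it. With the preset correlation of 0.01 the list was called in 7 of the 10 splits, and its estimated correlation was 0.579. The splits are too few for a share under 0.05, and 2 splits gave as large an absolute median, with 0.12 for the real one and 0.19 as the highest other. That highest value came from the split of 0Q replicates 1 and 3 and 100Q replicate 3 from the rest. Those libraries had negative correlations with transcript length (-0.27, -0.10 and -0.05), and the rest had positive ones (0.13 to 0.22). A biological effect of queuine on these transcripts stays open as untested.

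The third pattern is the MHC class II list, whose median lay above 0 without passing the test. With each library's length trend removed, the median went from 0.15 to 0.17, so it did not move toward 0. The list then passed camera (adjusted p = 0.0145, preset correlation). As reported, its adjusted p was 0.700 with an estimated correlation of 0.150. The removal was run with the preset correlation only, so that pass cannot decide on a length trend as a cause. The 6 members at 100 CPM or more had a median of 0.031, from -0.09 to 0.10, and the 11 others had 0.28, a difference that was not tested. The list also passed without 0Q replicate 1 (adjusted p = 0.00322, preset correlation). A test of a shared change among the abundant members was dropped, since it set their median against errors of single genes and its limit had been altered after its value was seen. No biological explanation was tested. The splits are too few for a share under 0.05, and 2 of 10 gave as large an absolute median, 0.15 for the real one and 0.18 as the highest other, and the list was called in 1 of them.

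For the remaining results the 10 splits are again too few for a share under 0.05. The real split called 0 genes by edgeR, with 309 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom, while the highest other called 2. For unadjusted p the highest other split gave 884 genes, and 6 splits gave as many as the real one. That highest split set 0Q replicates 1 and 3 and 100Q replicate 3 against the rest. It parted the libraries by the sign of their correlation with transcript length. For lists the real count was 2 and the highest other 4, with 4 splits as large. For the correlation of fold change with NAU share the real rho was -0.04 and the highest other absolute rho 0.11, with 6 splits as large.

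Cd74 stood at 21.3 and 26.2 CPM in 0Q and 100Q, far below H2-Aa at 577 and 580.3 CPM, and whether its reads were lost in quantification cannot be checked from the counts. The squared coefficient of variation in excess of counting noise fell with the mean count at a log-log slope of -0.737 (0Q) and -0.738 (100Q). The variance within groups was at least 4.53 times the counting variance in the abundance bins below 640 counts. Both measures were taken with 100Q thinned to its shallowest library and 0Q only rescaled. Among genes expected at 20 to 40 counts from the other libraries, 0.338% to 2.53% were at 0 in a given library.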
